A study of Mus musculus with 4 samples.

How the data were processed

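Gene expression was measured in 4 samples of mouse haematopoietic cells with 1-colour (Cy3) Agilent microarrays. Per the labels, long-term haematopoietic stem cells (LT-HSC, the CD34-negative Flt3-negative part of the lineage-negative, Sca-1-positive, Kit-positive marrow) or multipotent progenitors (MPP, the CD34-positive Flt3-positive part) were sorted from 10-week-old male C57BL/6J mice. The donors were wild type (WT) or carried a conditional knockout (cKO) of the kinase p38 alpha. The sorted cells were stained with the dye CFSE and transplanted into congenic mice irradiated with 9.5 Gy, and CFSE-positive cells were sorted again from the marrow after 16 h for RNA extraction. Each of the 4 groups (WT LT-HSC, WT MPP, cKO LT-HSC and cKO MPP) had 1 array, so no group had a replicate. The number of mice pooled for each array was not given in the sources used here.

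The deposited scanner tables held the authors' spot intensities on a linear scale from Agilent Feature Extraction 10.7.3.1, per the file headers; the submitters' processing notes give version 9.5.3. Per the file headers, the processed signal was background-subtracted and spatially detrended within each array, without scaling between arrays, and the array design was 028005 with probe coordinates on mouse build mm9. The authors' series table held ratios, linear signals relative to each probe's own level over the 4 arrays. Set against the scanner values, its entries were the processed signal times 1 factor per array and 1 factor per probe, within 0.01 (log2) for at least 99.998% of the probes of each pair of arrays, with the median of a probe over the arrays centred near 100.4. The differences between arrays had r = 1 across probes with those of the scanner values. The medians of its columns were 91.9 for WT LT-HSC, 107.3 for WT MPP, 97.5 for cKO LT-HSC and 102.4 for cKO MPP. The direction was the same as in the scanner values, the scaling between arrays lay close to the 75th percentile, and the rule behind it stayed unknown. Flags of the scanner software (score of 0 or 1 per spot, per the file headers) marked spots well above background, saturated spots and outliers.

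All 4 arrays lay on 1 slide and came from 1 scan, so slide and scan could not differ between groups. Each array had 59305 spots of 55681 non-control probes, and 137 to 151 spots per array were left out as outliers. The share of spots well above background was 68.3% for WT LT-HSC, 62.5% for WT MPP, 70.5% for cKO LT-HSC and 65.0% for cKO MPP, and 0 spots were saturated. Probes printed 10 times had a median SD between spots of 0.09 to 0.10 on the log2 scale, which covers printing and scanning only. The scanner software's own error of a log2 difference between 2 arrays had a median of 0.21 in each comparison. Neither error covers cells, sorts or RNA amplification, and the number of arrays limits the precision.

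Each spot's processed signal was put on the log2 scale and the array's 75th percentile over all non-control probes was subtracted, with spots of a probe averaged. Gene names came from the reference table of the GRCm38.p6 assembly, used for names only: 26756 probes matched by accession, 3824 by the symbol in the file and 639 by an older symbol, and 24462 kept the name in the file. A gene was represented by its probe with the highest mean over the 4 arrays among probes well above background on at least 1 array, which gave 28286 genes, of which 21527 were well above background on all 4 arrays. For 8615 genes more than 1 such probe existed. A gene well above background on only 1 of the 2 arrays compared was given a bound ("at least N-fold"): the brighter value against the higher of the dim probe's own value and the lowest signal well above background on that array.

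Pairs of arrays were compared by the log2 difference per gene, without p-values, and genes at 2-fold or more were counted in each direction. Differences shared by both populations or both genotypes were tested with limma 3.58.1 (R 4.3.3), with lmFit and eBayes on an additive model of genotype and population with 1 residual degree of freedom, over genes well above background on at least 2 arrays, and Benjamini-Hochberg adjustment at 0.05. In that fit a difference in response between the populations counts as error. On simulated data with the residual spread of the real arrays and 25838 genes, a shared genotype change of 1, 2, 3 or 4 on the log2 scale passed the threshold for 0% of the 50 genes planted at each size, although 56%, 86%, 100% and 100% of them reached an unadjusted p under 0.05. A count of 0 from this fit therefore says nothing about whether shared changes of these sizes exist in few genes. Larger numbers of changed genes were not simulated. The agreement of differences was described by correlations across genes, which are not independent replicates, and by the share of genes at 2-fold in both comparisons with the same direction, with a Wilson 95% interval. That interval treats genes as independent, so it is too narrow and covers neither arrays nor mice.

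Before the data were examined, 34 lists of pathway and cell type genes, the comparisons, the alternatives and the rule for named genes were fixed. Each list's median log2 difference over members measured on both arrays was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and members at 1.5-fold or more were counted. A list is called outside the random range below percentile 2.5 or above percentile 97.5, as a description of these arrays. Mapk14, Mitf and Impdh2 were named in every comparison. In each comparison the 10 genes with the highest and the 10 with the lowest difference were named, with the 5 largest bounds in each direction. For shared differences the rule took the 10 genes in each direction with the largest smaller difference, and of each list described up to 4 members with the largest absolute difference. Genes with a clone-like name were counted but not named. Some genes that these rules took are not reported here. After the data were examined, that last rule was widened to further accession-like names, and 4 marker lists were added for plasmacytoid dendritic cells, plasma cells, basophils with mast cells and eosinophils, and marrow stromal cells.

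The alternatives were quantile normalization, normexp background correction (offset 50) with quantile normalization, scaling on the 75th percentile or the median of probes well above background on all arrays, stricter and no filters on dim probes, the mean of a gene's probes, the authors' series table, thresholds of 1.5-fold and 3-fold, and other forms of the limma fit. Alternatives added after seeing the data were the brighter part of the genes, genes with at least 2 probes that moved together, and the genes left after removing those that differed between LT-HSC and MPP in both genotypes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots matplotlib 3.10.9.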

Results

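Expression was measured on 4 arrays, 1 for each combination of genotype (WT or cKO of p38 alpha) and cell population (LT-HSC or MPP), in CFSE-positive cells recovered 16 h after transplantation into irradiated mice. The study's title names p38 alpha, purine metabolism and the start of cycling in these cells. Between 62.5% and 70.5% of the spots of an array were well above background. With 1 array per group no difference between a pair of arrays has a replicate check, so differences are described by their size and a gene is called higher or lower on an array. Errors given with ± are the scanner software's own error of the difference.

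Mapk14, which encodes the targeted kinase p38 alpha, had 2 probes, both well above background on all 4 arrays. At the brighter probe (mm9 chromosome 17, 28873965 to 28874024) the processed signal was 1447 on the WT LT-HSC array, 912.2 on the cKO LT-HSC array, 951.2 on the WT MPP array and 1024 on the cKO MPP array. The cKO minus WT difference was -0.58 ± 0.20 (log2) in LT-HSC and 0.13 ± 0.20 in MPP. At the other probe (28885290 to 28885349) the differences were 0.13 and -0.03. With the mean of both probes the LT-HSC difference was -0.23. The labels do not say which exons were deleted, so neither probe checks the genotype labels, and cKO below means the array labelled cKO.

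Impdh2, an enzyme of guanine nucleotide synthesis from IMP, was lower on the cKO array in both populations. Its brighter probe (mm9 chromosome 9, 108467836 to 108467895) differed by -0.34 ± 0.20 in LT-HSC and -0.34 ± 0.20 in MPP. The other (108467842 to 108467901) differed by -0.32 and -0.19, but overlaps the first and is not a separate check. Over all genes measured on both arrays, the differences had an interquartile range of 0.71 in LT-HSC and 0.48 in MPP. Mitf, a transcription factor of the MiT family, gave opposite signs at its 2 probes. The brighter (mm9 chromosome 6, 97968501 to 97968560) differed by 0.16 ± 0.21 in LT-HSC and 0.28 ± 0.21 in MPP, and the dimmer by -1.01 and -0.24.

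The comparison of cKO with WT in LT-HSC asked which transcripts differed between stem cells of the 2 genotypes early after transplantation. Immediate early genes, which cells switch on within minutes of stimulation, were lower on the cKO array. The median of the list was -0.77 and 17 of its 21 measured members were lower by 1.5-fold or more, with 0 higher. Nr4a1 (-1.83 ± 0.20), Egr2, Atf3 and Nr4a2 had the largest differences of the list. Genes of pyrimidine and deoxynucleotide synthesis were mostly higher on the cKO array (median 0.64, 10 of 18 higher by 1.5-fold and 2 lower), among them Dctd (2.88) and Tyms (2.53), while Rrm2b stood at -1.98. A second probe of Dctd and of Rrm2b did not share the direction. Cd34, whose protein the sort used to part LT-HSC from MPP, was higher on the same array (1.71 at its brighter probe and 1.15 at the other, against -0.26 and -0.34 in MPP).

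Of the other metabolic lists, oxidative phosphorylation and one-carbon and serine metabolism lay above the random range on the cKO LT-HSC array. Like Cd34 and the pyrimidine list, both were lower on the WT LT-HSC array than on the WT MPP array. The 2 comparisons use the same WT LT-HSC array with opposite signs, so a deviation of that array alone would give both results. Oxidative phosphorylation had a median of 0.46, with 6 of 25 members higher by 1.5-fold and 0 lower, led by Ndufa9 (1.58) and Uqcrc2 (0.98). One-carbon and serine metabolism had a median of 0.43, with Fpgs at 2.47, Mthfd2 at 1.87 and Aldh1l2 at -1.89. Purine de novo synthesis had a median of 0.47 at percentile 97.3 of random lists, inside their range, with Prps2 at 3.63 and Adsl at 1.31. Glycolysis (0.18), the TCA cycle (0.14), purine salvage and breakdown (0.03) and the pentose phosphate pathway (-0.05) also lay inside it. The list from IMP to AMP and GMP had a median of -0.03, which changed sign with the percentile taken over probes well above background on all arrays. Its member Gmps stood at -0.69, with other probes at 1.42 and 1.77. G1/S and DNA replication genes (0.04) and G2/M genes (0.06) had medians inside the random range, and each changed sign under at least 1 other scaling.

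Cell type lists differed as well. On the cKO LT-HSC array stromal and endothelial genes were lower (median -1.86, 10 of 17 lower by 1.5-fold and 3 higher), with Cxcl12 at -4.60, Col1a1 at -4.30, Lepr at -3.87 and Emcn at -3.01. That median was -0.92 with normexp and quantile normalization, and a list of marrow stromal cell genes added after the data were examined stood at 0.43 (0.19 with members measured on 1 array at their bounds), inside the random range. B cell genes were lower (median -1.05, 10 of 15 lower by 1.5-fold, 0 higher), among them Igll1 (-2.20), Pax5 (-1.93) and Vpreb1 (-1.85). Erythroid genes had a median of -0.52, with Slc4a1 at -1.63 and Epor at -1.40, and genes of MPP and lymphoid priming a median of -0.44, with Lef1 at -3.30 (another probe at 0.40) and Satb1 at -1.89. Myeloid progenitor and granule genes were higher (median 0.31), with the gelatinase Mmp9 at 3.94, the lysozyme Lyz2 at 2.13 and Cebpe at 1.92. The p38 pathway list (-0.26), NF-kB and cytokine genes (-0.27) and interferon response genes (-0.16) also lay below the random range, but their members went both ways. By 1.5-fold, 6 p38 pathway genes were higher and 9 lower, 3 NF-kB and cytokine genes were higher and 8 lower, and 9 interferon response genes were higher and 9 lower. Rps6ka5 stood at 3.16, Ccl4 at -2.06 and Ifit2 at 2.78, so the first and last went against the median of their list. The NF-kB median was -0.0012 without a filter on dim probes, the p38 pathway median -0.13 with the mean of a gene's probes, and the priming median -0.14 with probes well above background on all arrays. With members measured on 1 array at their bounds, the NF-kB median was -0.10 and the priming median -0.27. In all, 4 of the 34 lists lay above the random range, 8 below it and 22 inside it, with T and NK cell genes (-0.23) exactly at percentile 2.5 and counted as inside.

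**Figure D1:**
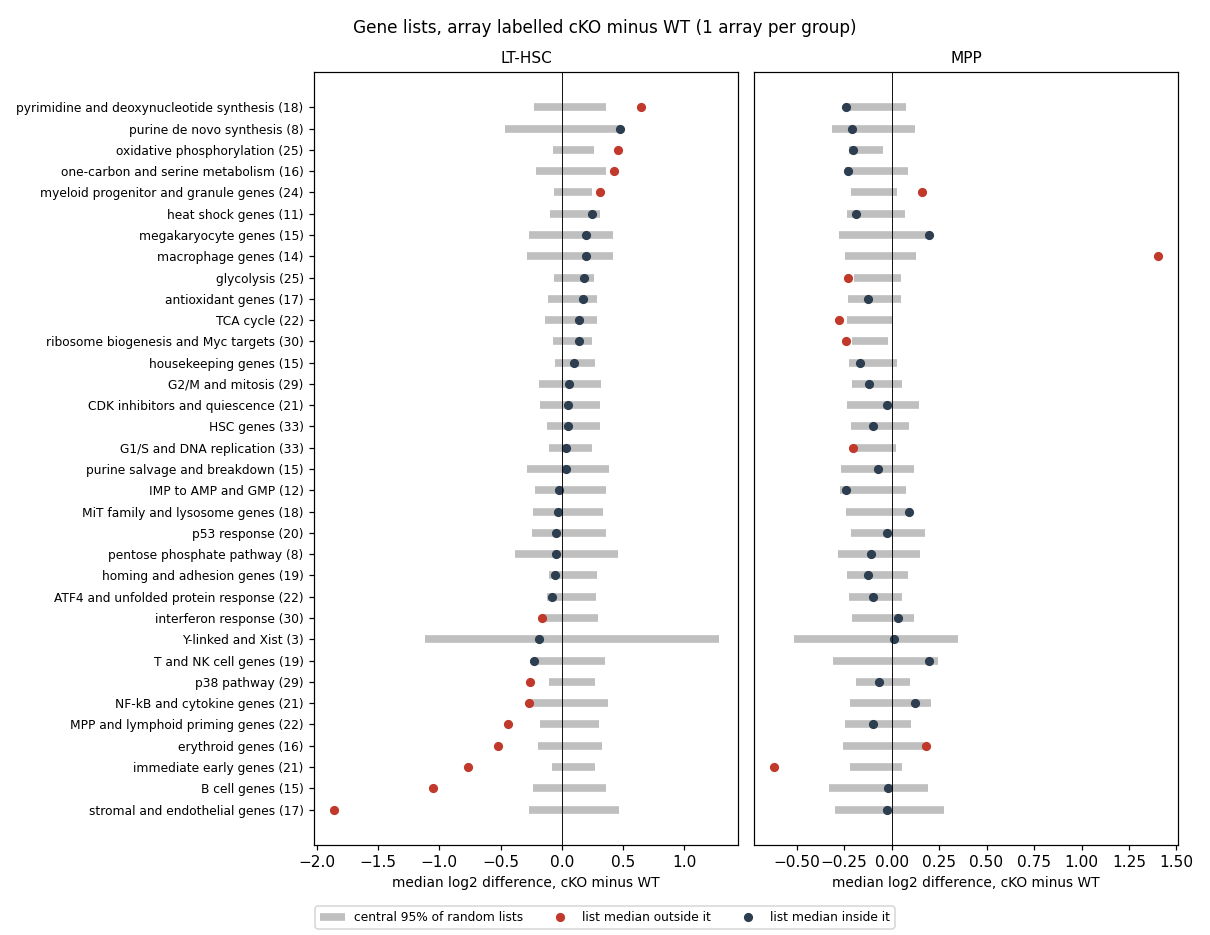
Median log2 difference, cKO minus WT, of the 34 gene lists (x axis) in LT-HSC (left) and MPP (right), with the number of members measured in LT-HSC in brackets. Grey bars span the central 95% of 10000 random lists matched on expression, and red points lie outside it, while T and NK cell genes in LT-HSC lie on its edge and are not red. Immediate early genes lie below it in both panels (-0.77 and -0.62), and macrophage genes lie far above it in MPP (1.40).

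In LT-HSC, 2992 genes were higher and 2279 lower by 2-fold or more on the cKO array, of which 828 and 373 by a bound. The largest positive differences were those of Gtpbp3, a mitochondrial tRNA modification enzyme (4.60 ± 0.32), Sirpb1a (4.56), Klra2 (4.41), Proca1 (4.36), Crispld2 (4.25), Afap1l1 (4.18), Fuom (4.09), Kctd11 (3.97), Nudt8 (3.96) and Mmp9. The largest negative ones were those of Cabcoco1 (-4.79 ± 0.26), the chemokine Cxcl12, Stimate (-4.58), Nrip2 (-4.50), the adhesion molecule Vcam1 (-4.32), the collagen Col1a1, Slc26a10 (-4.13), Zfp788 (-4.03), Pik3ip1 (-3.93) and the growth factor Pgf (-3.87). Other probes lay more than 2-fold nearer to 0 or went the other way for Crispld2 (-1.01), Proca1 (0.03), Kctd11 (0.59), Sirpb1a (1.04 and 3.39), Fuom (2.84) and Pik3ip1 (-1.10). By bounds, Trps1 was at least 50.6-fold higher, complement factor Cfb at least 46.0-fold, Esr1 at least 37.8-fold, Atp6v1g2 at least 28.5-fold and Syde1 at least 25.03-fold, but other probes of Trps1 differed by 1.49 and 2.32, that of Esr1 by -0.04 and that of Atp6v1g2 by -0.38. Igsf23 was at least 60.7-fold lower, Dnmt3l at least 29.4-fold, Cercam at least 23.7-fold, Senp6 at least 22.4-fold and Snhg20 at least 22.2-fold. With normexp and quantile normalization the counts were 920 higher and 1107 lower, which moved the higher share from 56.8% to 45.4%, and with quantile normalization alone it was 49.8%. Of 1008 genes with a second probe that reached 2-fold at the brightest probe, the second probe shared the direction in 68.4%. It reached 1.5-fold in that direction in 44.8%.

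The same comparison in MPP gave fewer and smaller differences. Macrophage genes were higher on the cKO array, with a median of 1.40 and 16 of 17 measured members higher by 1.5-fold or more. They included the complement component C1qc (1.82), the sialic acid receptor Siglec1 (1.56), the haem oxygenase Hmox1 (1.48) and the iron exporter Slc40a1 (1.46). Whether these transcripts came from the MPP or from macrophages in the sorted preparation was not tested. With 1 array per group, an effect of the genotype cannot be told apart from a difference between preparations. Immediate early genes were lower (median -0.62, 12 of 20 lower by 1.5-fold and 0 higher), with Fos at -1.36 ± 0.06, Nr4a1 at -1.28, Fosb at -1.24 and Jun at -1.08. Myeloid progenitor and granule genes were higher (median 0.16, 11 of 24 by 1.5-fold), with Lyz2 at 1.21, Chil3 at 1.18 and Ltf at 1.08. That median was 0.41 with the mean of a gene's probes.

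Of the metabolic and growth lists, 4 lay slightly below the random range on the cKO MPP array. The medians were -0.27 for the TCA cycle, -0.24 for ribosome biogenesis and Myc targets, -0.23 for glycolysis and -0.20 for G1/S and DNA replication. With normexp and quantile normalization they were -0.14, -0.14, -0.10 and -0.08. Sucla2 (-0.51), Srm (-0.58), Slc2a3 (-0.72) and Cdc25a (-0.59) were among their lowest members, and 0 members of the TCA and ribosome lists reached 1.5-fold. Purine de novo synthesis (-0.21) and the list from IMP to AMP and GMP (-0.24, with Gmps at -0.38) lay inside the random range, as did pyrimidine and deoxynucleotide synthesis (-0.24), one-carbon metabolism (-0.23), oxidative phosphorylation (-0.20), G2/M genes (-0.12) and the pentose phosphate pathway (-0.11). Housekeeping genes had a median of -0.16, with 14 of 15 lower, also inside it. Erythroid genes had a median of 0.18, above it, with Slc4a1 at 1.29, but of 0.09 with the mean of a gene's probes and -0.03 without a filter on dim probes. In all, 3 lists lay above the random range, 5 below it and 26 inside it.

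By count, 609 genes were higher and 703 lower by 2-fold or more in MPP. The highest were Cdc42bpa (2.57 ± 0.25), Ly6g5b (2.51), Gpr179 (2.502), Paqr9 (2.43), Klf12 (2.12), Depp1 (2.05), Gtpbp3 (2.05), Pira2 (1.98), Kash5 (1.955) and the transcription factor Maf (1.95). The lowest were Fam135a (-2.62 ± 0.28), the acute phase protein Orm1 (-2.48), Uba3 (-2.46), Rhox1 (-2.35), Parp3 (-2.18), the DNA sensor Aim2 (-2.16), Skint4 (-2.11), Tiam2 (-2.09), the kinase Prkca (-2.07) and Dync2h1 (-2.05). By bounds, Fam229b was at least 9.54-fold higher, the macrophage scavenger receptor Cd163 at least 9.35-fold, Cyp2c55 at least 7.15-fold, Olfr1057 at least 6.78-fold and Trib3 at least 6.69-fold. The eosinophil granule gene Prg2 was at least 19.8-fold lower, the basophil protease Prss34 at least 10.9-fold, Pfn2 at least 7.93-fold, Sult2b1 at least 7.31-fold and Pla2g5 at least 7.20-fold. With normexp and quantile normalization 102 genes were higher and 55 lower (65.0% higher, against 46.4%), and without a filter on dim probes 1689 and 2038. The higher share was 55.3% with the percentile over probes well above background on all arrays and 56.1% in the brighter genes. Some of the named genes had a signal near the lowest well above background, which was 15.4 on the WT MPP array and 12.8 on the cKO MPP array. Ly6g5b had 17.3 and Klf12 18.3 on the WT array, and Uba3 had 14.3 and Dync2h1 15.2 on the cKO array. Maf (83.0 on the WT array) and Prkca (75.4 on the cKO array) lay further from it. Other probes of Cdc42bpa lay between -0.63 and 0.08, that of Maf at -0.79, that of Pira2 at 0.96 and that of Prkca at -0.48. Of 154 genes with a second probe that reached 2-fold at the brightest probe, the second probe shared the direction in 64.3%. It reached 1.5-fold in that direction in 35.7%.

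**Figure D2:**
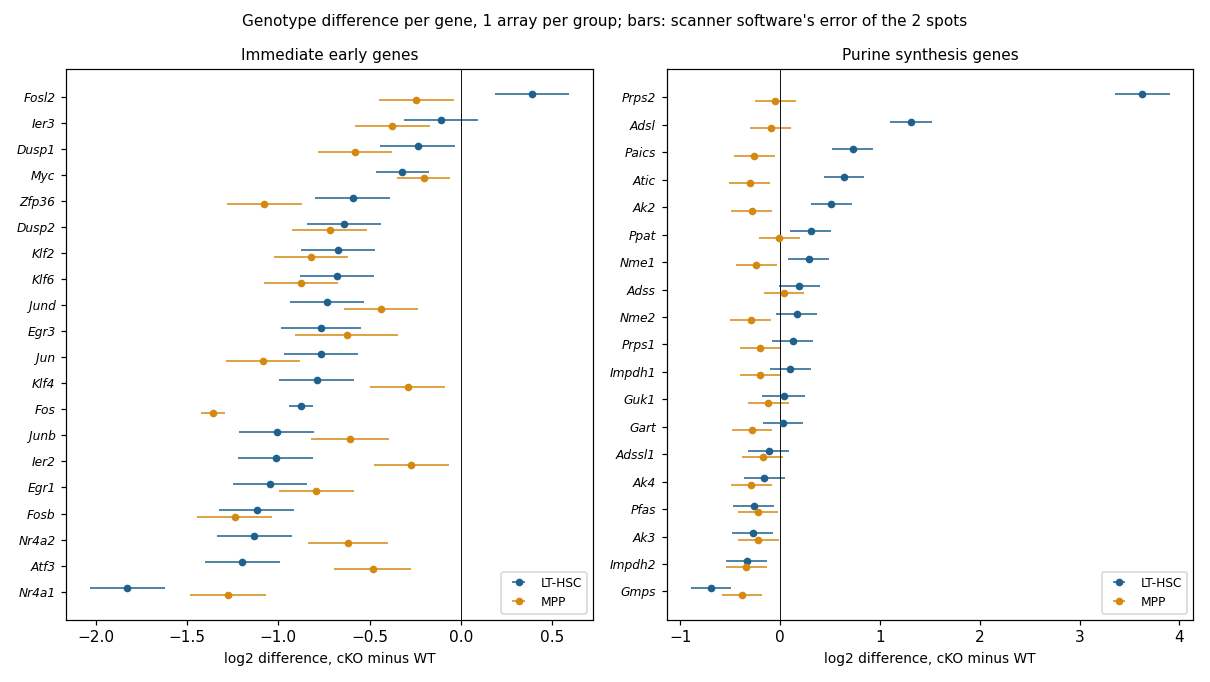
Log2 difference, cKO minus WT (x axis), of immediate early genes (left) and purine synthesis genes (right) in LT-HSC (blue) and MPP (orange), 1 array per group. Bars are the scanner software's error of the difference, not a replicate error. Of 20 immediate early genes measured in both populations, 19 lie below 0 in both.

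The differences of LT-HSC from MPP in WT cells compare 1 sorted preparation of each population without the knockout, whose cell make-up was not tested. They use the same WT LT-HSC array, with the opposite sign, as the comparison of cKO with WT in LT-HSC. Genes and lists that stand out in both are therefore not independent observations. Cd34, which the sort used to part them, was lower on the LT-HSC array by -2.99 ± 0.20. Flt3, the other receptor that parted them, differed by -1.81 at its brightest probe and by 0.22 and 0.88 at the other probes. The stem cell antigen Ly6a was higher (1.963). Genes of G2/M and mitosis were lower on the LT-HSC array (median -1.60, 25 of 29 lower by 1.5-fold and 0 higher), led by the cyclin Ccnb1 (-3.24), the checkpoint kinase Bub1 (-3.13) and Foxm1 (-3.06). G1/S and DNA replication genes were lower too (median -0.94, 22 of 33), with Pole at -2.74. Purine de novo synthesis was lower in 8 of 8 members by 1.5-fold (median -1.38), with Prps2 at -4.13 and Adsl at -2.13, and the list from IMP to AMP and GMP had a median of -1.02, with Impdh2 at -0.84.

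The WT LT-HSC array was also lower for one-carbon and serine metabolism (-1.47), pyrimidine and deoxynucleotide synthesis (-1.45), antioxidant genes (-1.23), ribosome biogenesis and Myc targets (-1.20), oxidative phosphorylation (-1.14), heat shock genes (-1.07), the TCA cycle (-1.06) and glycolysis (-1.04). Macrophage genes were lower as well (-1.03), with the scavenger receptor Marco at -4.05. Higher lists were B cell genes (median 4.14), NF-kB and cytokine genes (1.32), erythroid genes (1.19), T and NK cell genes (1.098), MPP and lymphoid priming genes (0.62), interferon response genes (0.60), myeloid progenitor and granule genes (0.45), immediate early genes (0.43), CDK inhibitors and quiescence genes (0.42) and homing and adhesion genes (0.37). The quiescence list was led by Foxo1 (3.44) and Btg1 (2.32), and the myeloid list was split, with Ly6c1 at 2.60 and Cebpa at -2.51. Stem cell genes had a median of 0.04, inside the random range. In all, 10 lists lay above that range, 13 below it and 11 inside it. Other scalings moved 16 of the 23 medians outside it by over 1.5 times without a change of sign. With normexp and quantile normalization glycolysis was at -0.46, the list from IMP to AMP and GMP at -0.52, G1/S genes at -0.58 and NF-kB genes at 0.70, while immediate early genes reached 0.92 with quantile normalization. The quiescence median was 0.08 with the mean of a gene's probes, and the T and NK cell median 3.41 without a filter on dim probes. With members measured on 1 array at their bounds, the T and NK cell median was 2.98, the priming median 0.97 and the stem cell median 0.09.

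By count, 2720 genes were higher and 4920 lower by 2-fold or more on the WT LT-HSC array. The highest were the lymphoid transcription factor Spib (7.33 ± 0.29), Gimap4 (7.16), Igh-VJ558 (7.03), the antibody joining chain Jchain (6.49), Klk1 (6.17), Upb1 (6.01), Klk1b5 (5.77), the erythroid carbonic anhydrase Car1 (5.68), Cxcl12 (5.49) and the B cell receptor component Cd79a (5.43). Among the lowest were Ccdc90b (-5.02 ± 0.28), Epb41l3 (-4.93), Trmt11 (-4.69), Fbp1 (-4.51), Mecr (-4.48), Oxnad1 (-4.37), Nudt8 (-4.36), Afap1l1 (-4.24) and the repair gene Ercc1 (-4.22). Ercc1 (17.8) and Afap1l1 (18.2) on the WT LT-HSC array and Upb1 (18.6) on the WT MPP array had signals near background. Other probes of Car1 (3.27) and Ccdc90b (-1.06) lay nearer to 0. By bounds, the interleukin receptor chain Il2rb was at least 252-fold higher, Ccr9 at least 128-fold, Igkv4-53 at least 125-fold, Cd2 at least 116-fold and Olfr164 at least 76.7-fold. Trps1 was at least 57.1-fold lower (other probes at -2.37 and -2.36), Pafah2 at least 25.8-fold, Cpq at least 24.9-fold, Hsdl1 at least 22.4-fold and Pcgf6 at least 22.0-fold. The higher share was 35.6%, against 45.6% with quantile normalization, 49.9% with normexp (1750 higher and 1758 lower) and 45.9% with the percentile over probes well above background on all arrays. These scalings moved the median over the 30979 probes well above background on all arrays by 0.13, 0.17 and 0.15.

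In cKO cells the LT-HSC array differed from the MPP array in many of these lists too. G2/M genes were lower (median -1.17, 23 of 29 by 1.5-fold, 0 higher), with Ttk at -2.50 and Ccnb1 at -2.27. Purine de novo synthesis (-0.84), the TCA cycle (-0.74), ribosome biogenesis and Myc targets (-0.73), the list from IMP to AMP and GMP (-0.72, Impdh2 at -0.84), antioxidant genes (-0.65), oxidative phosphorylation (-0.63), glycolysis (-0.53), one-carbon metabolism (-0.53) and G1/S genes (-0.52) lay below the random range, as did housekeeping genes (-0.57). Macrophage genes were lowest (median -2.12), with Vcam1 at -7.10, Marco at -4.62 and Hmox1 at -4.18. B cell genes (2.32), T and NK cell genes (1.14), myeloid genes (0.81), immediate early genes (0.69), interferon response genes (0.54), NF-kB and cytokine genes (0.53), megakaryocyte genes (0.48), erythroid genes (0.36), homing genes (0.30), MPP and lymphoid priming genes (0.25) and quiescence genes (0.17) lay above it. Other scalings moved 12 of these 23 medians by over 1.5 times without a change of sign, with housekeeping genes at -0.24, one-carbon metabolism at -0.27 and quiescence genes at 0.05 with normexp and quantile normalization. The quiescence median was 0.60 with the mean of a gene's probes. The T and NK cell median was 0.63 with probes well above background on all arrays and 2.71 without a filter on dim probes. Cd34 differed by -1.02 ± 0.20, Flt3 by -1.16 at its brightest probe and by 0.70 and 0.63 at the others, and Ly6a by 2.11.

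In cKO cells 2197 genes were higher and 1808 lower by 2-fold or more on the LT-HSC array. The highest were Jchain (6.68 ± 0.22), Spib (6.07), Igh-VJ558 (5.96), Gimap4 (5.56), Il2rb (5.47), the B cell coactivator Pou2af1 (5.31), Fcmr (4.80), Tubb3 (4.79), the MHC class II gene H2-Aa (4.67) and Sdc4 (4.60). The lowest were Vcam1, Marco, Hmox1, Oxnad1 (-4.04), the iron exporter Slc40a1 (-3.81), the macrophage protein Cd5l (-3.79), Gpd1 (-3.78), the complement gene C1qc (-3.60), S1pr3 (-3.41) and Zbtb24 (-3.23). By bounds, Igkv4-53 was at least 122-fold higher, Cd2 at least 88.3-fold, Upb1 at least 48.2-fold, Olfr164 at least 47.6-fold and Proca1 at least 44.4-fold. Another probe of Proca1 differed by 0.03, and another of Gimap4 by 3.42. Fcna was at least 22.0-fold lower, Paqr9 at least 13.5-fold, Fam229b at least 13.2-fold, Cd163 at least 12.9-fold and Slco2b1 at least 12.8-fold. The higher share was 54.9%, against 68.3% with normexp (957 higher and 445 lower) and 65.5% with the percentile over probes well above background on all arrays, which moved the median over those probes by 0.11. The majority turned to lower at 1.5-fold (45.2% higher), with probes well above background on all arrays (49.2%), in the brighter genes (48.4%) and for genes whose probes all moved the same way (47.2%).

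**Figure D3:**
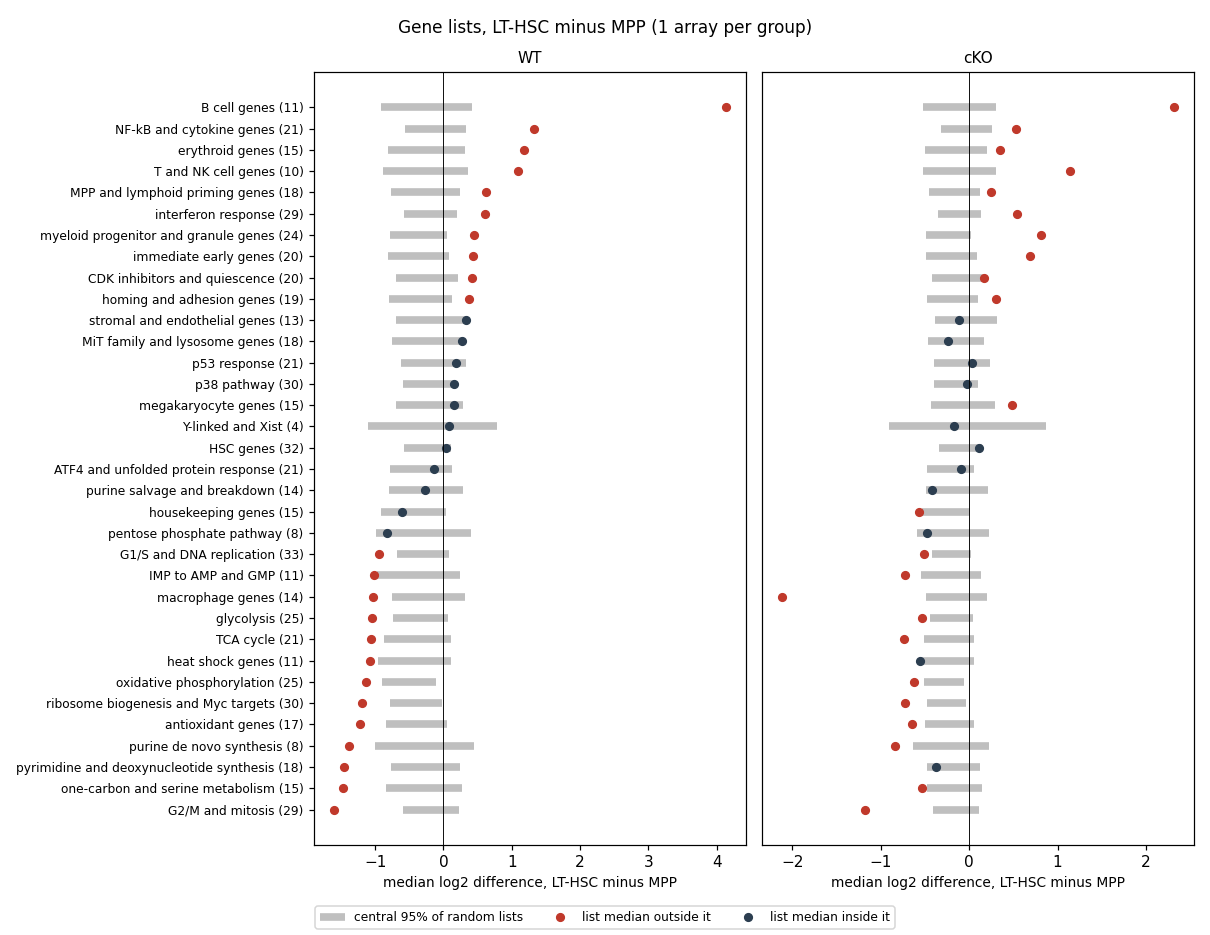
Median log2 difference, LT-HSC minus MPP, of the 34 gene lists (x axis) in WT (left) and cKO (right), with the number of members measured in WT in brackets. Grey bars span the central 95% of 10000 random lists matched on expression, and red points lie outside it. B cell genes lie highest in both panels (4.14 and 2.32), and G2/M genes lie lowest in WT (-1.60) and macrophage genes in cKO (-2.12).

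The genotype differences of the 2 populations showed little relation to each other. Across 21527 genes, which are not independent replicates, Pearson's r was 0.02 and Spearman's rho 0.02. Of 276 genes at 2-fold or more in both, 142 (51.4%, Wilson 95% interval 45.6% to 57.3%, with genes taken as independent) had the same direction. In the additive limma fit 0 of 25838 genes passed an adjusted p of 0.05 for genotype (smallest adjusted p = 0.973), 935 genes had an unadjusted p under 0.05, and 0 passed adjusted over the list alone in any of the 34 lists. The other forms of the limma fit also gave 0.

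Immediate early genes lay below the random range in both populations and myeloid progenitor and granule genes above it in both. Of the immediate early genes, 19 of 20 were lower on both cKO arrays and 12 of 20 by 1.5-fold in both, and of the myeloid genes 13 of 24 were higher on both and 3 of 24 by 1.5-fold. In the limma fit Nr4a1 had a shared difference of -1.55 ± 0.31 (SE), Fosb -1.18 ± 0.27 and Fos -1.12 ± 0.30, each with adjusted p = 0.123 adjusted over the list alone. By the smaller of the 2 differences, the genes highest on both cKO arrays were Ly6g5b (3.20 in LT-HSC and 2.51 in MPP), Gtpbp3, the chemokine Ccl6 (2.71 and 1.66), Tmcc3 (3.72 and 1.64), the macrophage gene Aif1 (1.49 and 1.46), Lima1, Crispld2, Prlr, the inflammasome sensor Nlrp3 (1.26 and 1.52) and Zfp108. The lowest were Hopx (-2.17 and -1.98), Crybg1 (-2.19 and -1.70), Sh3pxd2b, the endothelial gene Emcn (-3.01 and -1.61), Spock2, Sass6, Mamdc2, the pre-B cell gene Vpreb1 (-1.85 and -1.46), the kinase Lyn (-2.02 and -1.38) and Prkca. Another probe of Crispld2 went the other way in both (-1.01 and -0.72), and another of Prkca stood at 0.40 and -0.48. The adjusted p over all genes was 0.973 for the genes named here. Ly6g5b had signals near background on both WT arrays (15.6 in LT-HSC and 17.3 in MPP), as had Gtpbp3 (16.3 and 21.3).

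The population differences of the 2 genotypes were closer to each other. Across the same 21527 genes r was 0.57 and rho 0.49, and 1393 of 1570 genes at 2-fold in both (88.7%, Wilson 95% interval 87.1% to 90.2%, with genes taken as independent) had the same direction. In the additive limma fit 0 of 25838 genes passed for population (smallest adjusted p = 0.0636), with 4103 genes at an unadjusted p under 0.05. Other settings passed up to 198 genes (with an intensity trend in eBayes). Adjusted over the list alone, 57 list members rose in LT-HSC against MPP and 27 fell, in 11 of the 34 lists. They included 13 of 15 B cell genes and 13 of 19 T and NK cell genes, all higher, 13 of 29 G2/M genes and 5 of 18 macrophage genes, all lower, and 2 of 12 genes from IMP to AMP and GMP, both lower. Among MPP and lymphoid priming genes 10 of 23 passed (9 higher and 1 lower). Myeloid progenitor and granule genes were split, with 13 of 24 passing (8 higher and 5 lower). The adjustment was not extended across the 34 lists. The fit took values not well above background as they stood, without bounds. Only 10 of 15 B cell genes and 9 of 20 T and NK cell genes were well above background on both MPP arrays. Some of these calls therefore rest on MPP values near background.

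By the smaller of the 2 differences, the genes highest on both LT-HSC arrays were Jchain (6.49 in WT and 6.68 in cKO), Spib, Igh-VJ558, Gimap4, Pou2af1, Fcmr, Mzb1 (4.63 and 4.49), Cd79a (5.43 and 4.44), Car1 and Ly6d. The lowest were Marco (-4.05 and -4.62), Oxnad1, S1pr3, Prxl2b, Egln3, Slc40a1, Dnajc6, Ticrr, the interleukin receptor Il1r1 and the mitotic cyclin Ccnb1 (-3.24 and -2.27). Another probe of Ticrr stood at -0.80 and -0.42, and those of Ccnb1 between -1.94 and -1.49 in WT and between -1.67 and -0.90 in cKO.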

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

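Of the tests below, those of plasmacytoid dendritic cell markers and of immediate early genes under other scalings were set before their results were seen, and the others after.

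Some differences between the arrays labelled cKO and WT had opposite signs in the populations, and with 1 array per group the difference between them was not tested. The list medians in LT-HSC and MPP were 0.64 and -0.24 for pyrimidine and deoxynucleotide synthesis, 0.43 and -0.23 for one-carbon and serine metabolism, and -0.52 and 0.18 for erythroid genes. The first 2 MPP medians lay inside the random range, and that of pyrimidine and deoxynucleotide synthesis was -0.05 with normexp and quantile normalization. The erythroid MPP median was -0.03 without a filter on dim probes, so its opposite sign did not hold there. Aim2 differed by 1.61 in LT-HSC and -2.16 in MPP, Klf12 by -1.31 and 2.12, Sirpb1a by 4.56 and -1.05, and Vcam1 by -4.32 and 1.44. Between LT-HSC and MPP, Zbtb24 differed by 1.98 in WT and -3.23 in cKO, which was not tested either. Most of these genes had a signal near the lowest well above background on 1 array. These were Klf12 on the WT MPP array (18.3), Sirpb1a on the WT LT-HSC array (16.1), and Vcam1 and Zbtb24 on the cKO LT-HSC array. Other probes of Sirpb1a stood at 1.04 and 3.39 in LT-HSC. No other probe was available for Klf12 and Aim2 in MPP, Vcam1 in LT-HSC or Zbtb24 in cKO.

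B cell genes were far higher on both LT-HSC arrays than on the MPP arrays, with processed signals of 18587 (WT) and 11853 (cKO) for Cd74 and 5306 and 2570 for Cd79a on the LT-HSC arrays, against 726.7 and 102.8 on the WT MPP array. Sampling of few transcripts would send members both ways. The B cell genes measured on all arrays were 10 of 15, and 100% of these were higher in LT-HSC in both genotypes. That test was set after these genes were seen to be higher, and it restates the pattern. It could hardly have come out otherwise, so it does not decide on sampling. Scaling would bring the list median near 0, but its smallest value over 6 scalings and both genotypes was 1.54. Cells of these types among the LT-HSC sorts may be the source. Markers of plasmacytoid dendritic cells, of which 12 of 15 were also well above background on both MPP arrays, had medians above the random range in both genotypes, the smaller being 0.69. That list was added after genes of these cell types were seen to be high on the same arrays. Transcription of such genes within the LT-HSC would raise it as well, so it does not tell the sources apart. The sort of lineage-negative, Sca-1-positive, Kit-positive cells before the dye was added should remove such donor cells. The later sort of CFSE-positive cells should remove those of the recipient only if none had taken up the dye, and would not remove donor cells carried along. Whether other cells passed these sorts was not tested. Transcription of lymphoid genes within the LT-HSC themselves stays open and was not tested.

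Immediate early genes were lower on both arrays labelled cKO. The median stayed at or below -0.42 over 6 scalings and both populations, so the choice among these scalings does not account for the difference. In these comparisons they shifted the median over probes well above background on all arrays by only -0.09 to 0.06. This test could therefore hardly have come out otherwise. Fewer macrophages in the cKO sort is argued against in MPP by the macrophage median of 1.40, but not in LT-HSC, where it was 0.20, with 7 members higher and 7 lower, and where B cell (-1.05), stromal and endothelial (-1.86) and erythroid genes (-0.52) were lower with the immediate early genes. Different handling stress could not be excluded, since genotype and preparation go together on these arrays, and the heat shock medians had opposite signs, 0.25 in LT-HSC with 10 of 11 members higher and -0.19 in MPP with 11 of 11 lower, both inside the random range. An effect of the genotype itself stays open and was not tested apart from the preparation.

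The spread of the cKO against WT difference was wider in LT-HSC than in MPP, with a ratio of interquartile ranges of 1.49 over all genes. Sampling of few transcripts on the LT-HSC arrays might widen it, and in the brightest of 10 equal groups of genes the ratio was 1.06. The largest ratio, 1.90, lay in the middle of the brightness range and the dimmest group had 1.13, so the cause cannot be told apart from a larger difference between the genotypes in LT-HSC.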

How the results depend on the processing

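The brighter genes and the genes with several probes in accord were chosen as alternatives after seeing the data. Of 528 values of the 66 list medians outside the random range, 1 changed sign under an alternative: the erythroid median in MPP, cKO against WT, was -0.0295 without a filter on dim probes. Of 560 values of the 70 medians inside it, 51 changed sign, in 25 medians. Of 1479 values of single genes, 1211 stayed close, 266 moved and 2 reversed when probes had to be well above background on all arrays, which takes another probe: Esr1 (-0.0382) and Atp6v1g2 (-0.38) in LT-HSC. With the mean of probes Mapk14 in LT-HSC was -0.23, and smaller differences changed sign for Mitf (-0.43 in LT-HSC and -0.32 within cKO) and Mapk14 (-0.15 within WT).

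Counts of genes follow as higher and lower on the first array named, for cKO against WT in LT-HSC, the same in MPP, LT-HSC against MPP in WT, and the same in cKO. At 1.5-fold they were 5957 and 4187, 2003 and 2495, 4602 and 8425, and 4273 and 5185. At 3-fold they were 1319 and 965, 134 and 145, 1517 and 1962, and 1068 and 461. With normexp and quantile normalization they were 920 and 1107, 102 and 55, 1750 and 1758, and 957 and 445. In the brighter genes they were 1118 and 983, 179 and 140, 1312 and 2995, and 836 and 890. For genes with at least 2 probes that all reached 1.5-fold the same way they were 201 and 168, 19 and 25, 253 and 655, and 150 and 168. With probes well above background on all arrays they were 1985 and 1630, 344 and 373, 1940 and 3993, and 1339 and 1383. Without a filter they were 4407 and 3072, 1689 and 2038, 3652 and 6354, and 3572 and 2790. Thresholds and filters set these counts by construction, and the cause of the other moves was not tested.

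The shared population difference passed for 0 genes as reported, 198 with an intensity trend, 194 with population alone in the model, 156 with the mean of probes, 101 with the percentile over probes well above background on all arrays, 68 with probes well above background on all arrays and 57 with normexp, and the cause was not tested. With normexp the share with the same direction in both genotypes was 96.0%. The slide as a block was not run, since all 4 arrays lay on 1 slide, and no array could be left out of a group of 1. The additive fit pairs the LT-HSC and MPP arrays of each genotype, and the fit with population alone leaves the pairs out. Signal near background limits dim genes, for which bounds depend on the lowest signal well above background.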

Other observations

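The lists in this part were chosen after seeing the data. Genes of plasmacytoid dendritic cells were higher on the LT-HSC arrays than on the MPP arrays (median 1.66 in WT and 0.69 in cKO), with Pld4 at 4.57 and 3.88, and lower on the cKO than on the WT array in LT-HSC (-0.35, against -0.01 in MPP). Plasma cell genes had cKO minus WT medians of -0.62 in LT-HSC and -0.38 in MPP, both below the random range, and LT-HSC minus MPP medians of 0.17 in WT and -0.11 in cKO, or 0.89 and 0.25 with members measured on 1 array at their bounds. Genes of basophils, mast cells and eosinophils had cKO minus WT medians of 0.21 and 0.03, and LT-HSC minus MPP medians of -0.18 and -0.45. With such members at their bounds the last 3 were -0.05, -0.04 and 0.09. Marrow stromal cell genes had cKO minus WT medians of 0.43 in LT-HSC and 0.15 in MPP, inside the random range, where the stromal and endothelial list fixed earlier stood at -1.86 in LT-HSC. Their LT-HSC minus MPP medians, over 6 of 15 genes, were -0.07 in WT and -0.19 in cKO. With bounds the cKO minus WT median in LT-HSC was 0.19 and the LT-HSC minus MPP median in WT 0.17.

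Probes of Siglech, a receptor of plasmacytoid dendritic cells, disagreed. The brightest differed by -0.02 between LT-HSC and MPP in WT, while the other probes, not well above background on the MPP arrays, had LT-HSC signals of 958.1 and 426.0 in WT. The housekeeping gene Tbp was lower on the WT LT-HSC array than on the WT MPP array (-2.98) and than on the cKO LT-HSC array, where cKO minus WT was 1.75.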
